A study of Homo sapiens with 22 samples.

How the data were processed

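Messenger RNA was measured in 22 libraries of 4 human progenitor populations. Per the labels, cells were sorted by flow cytometry from CD34-selected blood of G-CSF mobilized donors, RNA was extracted with RNAqueous-Micro, and libraries were made with the TruSeq Stranded mRNA kit. The common myeloid progenitor (CMP), the megakaryocytic-erythroid progenitor (MEP) and the erythroid progenitor (ERP) each had 6 libraries from 4 donors. The megakaryocyte progenitor (MKP) had 4 libraries from 2 donors. Where 1 donor gave more than 1 library of a population, the design notes describe them as further sorts.

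The authors deposited 1 table of raw read counts per gene symbol and library, with no normalisation. Their notes name STAR 2.7.7a, HTSeq 0.13.5, DESeq2 without a version, and the genome build hg38. They give neither the annotation release nor the strand setting of the count. Each deposited table of counts held 56614 rows, of which 5 were summary rows of the counting program and 56609 were genes. Groups and donors were taken from the sample labels. For the 12 samples labelled MEP or ERP, the name of the deposited table gave the other of these populations. Values below follow the labels, and an alternative exchanged the names.

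Before any test, 1180 gene rows that can carry a donor's sex or genotype were left out, namely genes of the Y chromosome, X inactivation transcripts, HLA genes, antigen receptor segments, blood group genes and genes with common whole-gene deletions. The other 55429 rows were used. Coordinates came from GENCODE 29 on GRCh38, in which 96.9% of the gene names were found. Reads in genes ranged from 2362581 to 36083998 per library. A count of 0 reads allows up to 3 reads, and such limits and counting intervals (exact, 95%) cover counting error only, since reads without molecular identifiers are not independent molecules. A fold against a group with 0 reads was computed against 3 reads over the summed depth of that group and written as a lower bound. The reads of the other group were summed over its libraries too, so that deep libraries weigh more. Where the mean over donors gave a lower bound, that is printed beside it.

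Counts were analysed with R 4.3.3 and edgeR 4.0.16. All 22 libraries were fitted together with 1 term per population, TMM factors, the filterByExpr filter and the quasi-likelihood F test. This left 20133 genes. P-values were adjusted over these genes by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. The main comparisons were MEP with CMP, ERP with MEP, MKP with MEP, and MKP with ERP. ERP with CMP and MKP with CMP were secondary. Fold changes are log2 values from this fit with their standard error (SE). Levels are CPM, read counts scaled to the reads of the library in the genes kept by the filter times its TMM factor, as edgeR's cpm function gives them, averaged within a donor and then over donors, with the SD between donors (n = 4, and n = 2 for MKP).

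Libraries of 1 donor share a donor term that this fit leaves out, so each count of changed genes is given beside that of a fit with the donor as a block, and the count of a list where the block moved it by over 1.5 times. The labels' pairing was checked once. After removal of the population means, libraries of the same donor and different populations correlated across genes at 0.424 to 0.796 (median 0.646), and those of different donors at −0.688 to 0.675 (median −0.454). All 22 libraries correlated best with another library of their own donor. Counts of library pairs of the same donor and population were compared by a chi-square per gene, over genes with at least 50 reads, where 1 is expected from sampling alone. It averaged 1.63 to 1.85 in 4 pairs and 33.7 to 142 in 4 further pairs, all of 1 donor. Library pairs of different donors in the same class gave 16.4 to 112. The 4 closest pairs may be technical repeats, although the design notes describe further sorts, and the labels do not settle it. All pairs were beyond sampling noise and were kept apart, which counts them as separate replicates, and an alternative summed them.

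26 gene lists were written before the data were examined, as were the comparisons, tests and rules for naming genes. They cover erythroid genes, heme synthesis and iron import, megakaryocyte and platelet genes, RUNX1 targets in megakaryocytes, the RUNX and core binding factor family, kinases and phosphatases acting on RUNX1, P-TEFb and transcription kinases, and megakaryocytic-erythroid transcription factors. Others cover stem and multipotent progenitor genes, granulocyte and monocyte progenitor genes, and lymphoid, mature monocyte, dendritic, T and NK, endothelial, and basophil, mast cell and eosinophil genes. The remaining lists are S phase, G2 and M phase, ribosome biogenesis and MYC, surface proteins used in sorting, cytokine receptors and signalling, cholesterol synthesis, interferon response, immediate early and heat shock, oxidative phosphorylation, and the actin, myosin and integrin cytoskeleton. Each list was tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated per list, adjusted over the 26 lists.

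Genes were named by rule. In each main comparison these were the 6 largest rises and 6 largest falls among called protein-coding genes with at least 10 CPM in the higher group and no overlap between the libraries of the groups. To them were added the 3 called members with the smallest adjusted p of each list described, and 6 fixed genes, RUNX1, CBFB, CDK9, GATA1, KLF1 and FLI1. Some further genes that these rules name are not reported here. The labels of MEP and ERP were checked with the mean log2 CPM (prior count 2) of the erythroid list per library and a two-sided exact permutation test.

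Alternatives were DESeq2 size factors, no filter on low counts, at least 1 CPM in 4 libraries, the Wald test of DESeq2 1.42.0, a fit of the compared groups alone, blocks by donor or by replicate number, libraries summed per donor, the 2 donors with all populations, each donor or MKP library left out, a fold threshold, and exchanged MEP and ERP names. Fits within library classes, and summed libraries with a donor block, were added after the data were examined. The procedure was tested on simulated data with known changes. Of 4-fold changes, the fit recovered 32.8% in MEP with CMP and 16.4% in MKP with ERP at the spread of the fit without a donor term, and of 16-fold changes 75.8% and 64.6%. False calls made up 2.6% and 0% of the calls. Each simulated library was drawn independently, with no donor or class effect. False calls that come from taking libraries of 1 donor as replicates were therefore not tested. Figures were drawn with matplotlib 3.10.9.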

Results

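RNA was sequenced from 4 populations of blood progenitors on the path from the common myeloid progenitor (CMP) to red cells and platelets. The megakaryocytic-erythroid progenitor (MEP) gives rise to both lineages, the erythroid progenitor (ERP) to red cells and the megakaryocyte progenitor (MKP) to the cells that shed platelets. CMP, MEP and ERP had 6 libraries each from 4 donors, and MKP had 4 libraries from 2 of these donors. Reads in genes per library ranged from 2920244 to 23899144 in CMP, from 3360876 to 24621583 in MEP, from 2951155 to 36083998 in ERP and from 2362581 to 32861463 in MKP. MEP and ERP are named as the sample labels name them. The names of the 12 deposited tables of these samples give the opposite.

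Libraries fell into 2 classes by their share of reads outside annotated genes. It was 53.0% to 61.9% in 14 libraries of 3 donors and 15.6% to 21.2% in 8 libraries of 1 donor. Both classes held all 4 populations. The 14 libraries detected 20373 to 28751 genes and the 8 libraries 14870 to 22734. Mitochondrial genes took 0.899% to 3.76% of gene reads in the 14 libraries and 6.64% to 9.27% in the 8 libraries. For some genes changes are therefore also given within each class, as the value in the 14 libraries and then that in the 8 libraries. In the 14 libraries MKP came from 1 donor and the other populations from 3 donors. Class values with MKP there mix the difference between populations with that between donors.

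**Figure D1:**
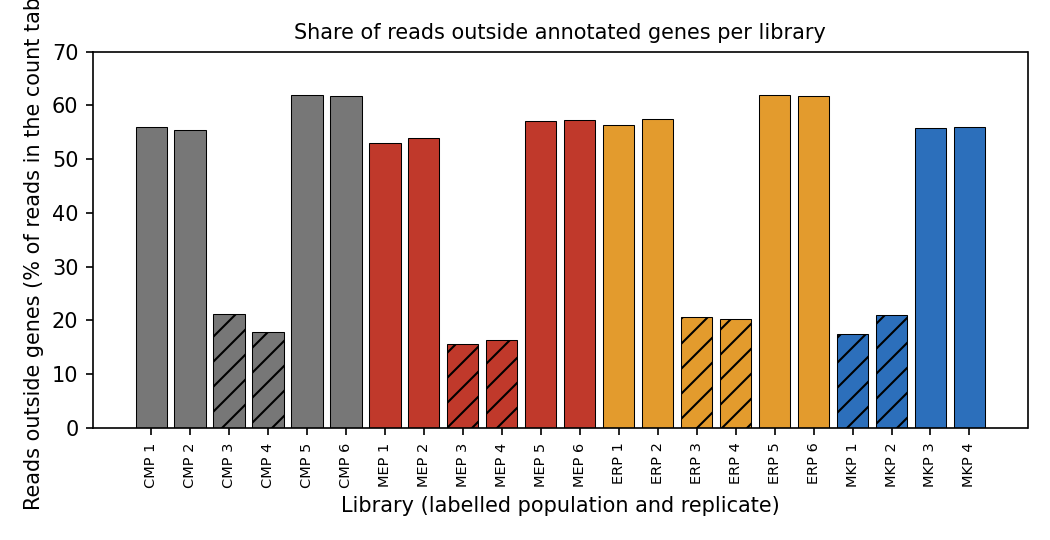
Percent of the reads in the count table that lay outside annotated genes, 1 bar per library, grouped by labelled population, with the 8 libraries of 1 donor hatched. The hatched bars lie between 15.6% and 21.2% and the others between 53.0% and 61.9%, in all 4 populations.

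Erythroid genes were higher in the libraries labelled MEP than in those labelled ERP. Over the 22 tested genes of the erythroid list, the mean log2 CPM per library was 6.05 ± 0.55 (SD, n = 6) in libraries labelled MEP and 2.71 ± 0.67 (n = 6) in those labelled ERP. The difference, ERP minus MEP, was −3.34 (two-sided exact permutation p = 0.00216 over 924 regroupings). This test takes libraries of 1 donor as independent, and with means per donor permuted within donors the difference was −3.43 (exact permutation p = 0.125, the smallest that 4 pairs allow). The lowest library labelled MEP lay at 5.38 and the highest labelled ERP at 3.31, and labelled MEP was higher in 4 of 4 donors. Within the 14 libraries the exact permutation p was 0.0286, the smallest that 70 regroupings allow, and within the 8 libraries it was 0.333, the smallest that 6 allow. Among genes set for this check, CD36, a surface protein of maturing erythroid cells, was at 195 ± 91.2 CPM (SD, n = 4) in labelled MEP and at 4.06 ± 3.89 CPM (n = 4) in labelled ERP. The beta-globin gene HBB was at 22.2 ± 15.0 CPM and 0.279 ± 0.351 CPM. By the names of the deposited tables, these genes were higher in ERP than in MEP.

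**Figure D2:**
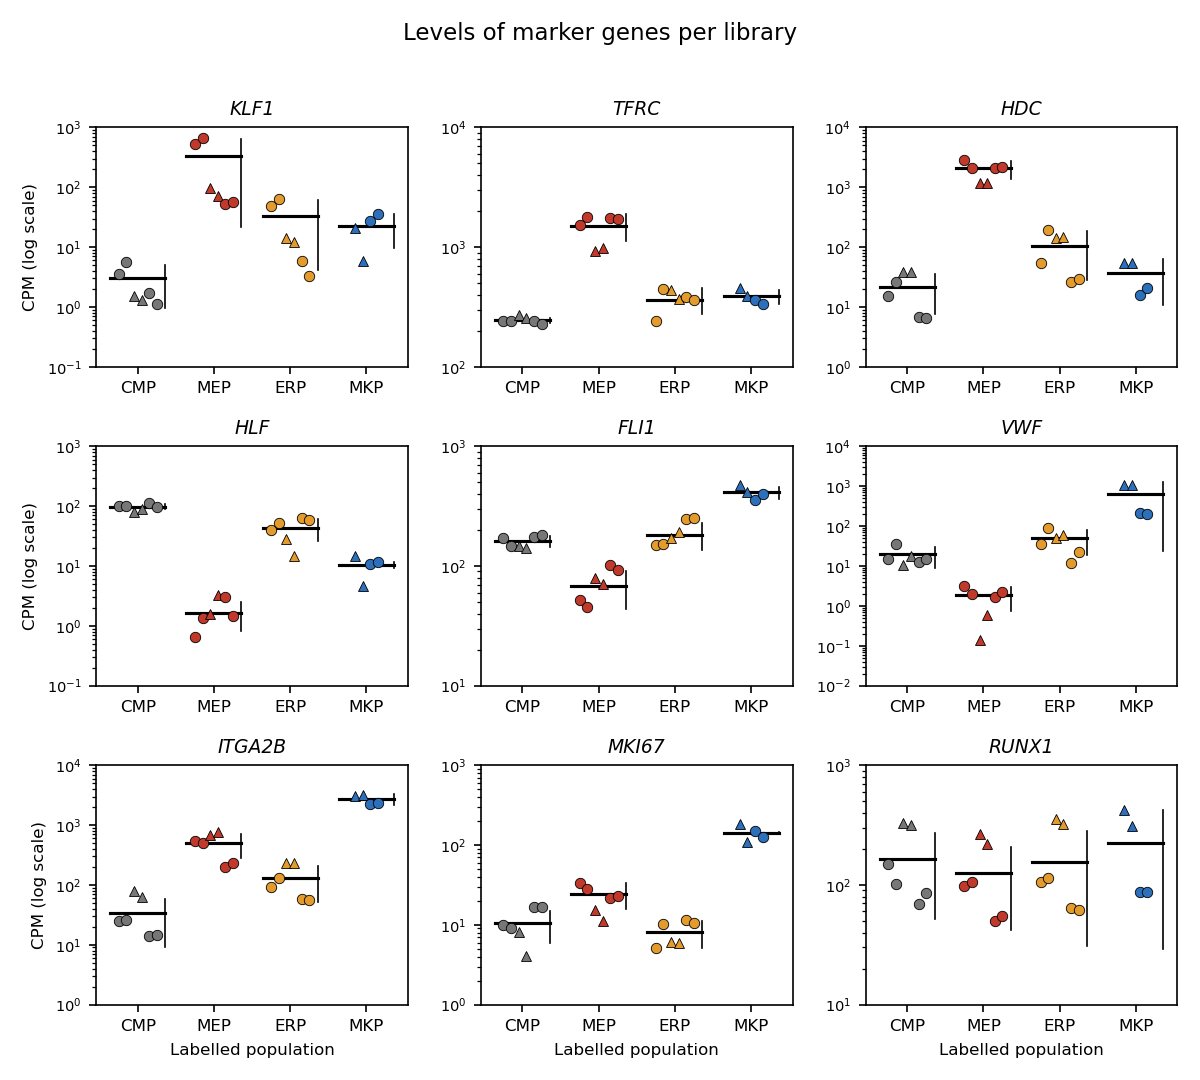
Levels of 9 genes in CPM (log axis) by labelled population, with 1 point per library, triangles for the 8 libraries of 1 donor and circles for the 14 others, a horizontal line for the mean over donors and a vertical line at its right end for ± 1 SD between donors (n = 4, n = 2 for MKP). KLF1, TFRC and HDC were higher in libraries labelled MEP than in those labelled ERP, at group means of 332, 1496 and 2068 CPM against 32.4, 365 and 106 CPM.

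With adjusted p under 0.05 in edgeR's quasi-likelihood test, 1251 of 20133 genes changed in MEP against CMP, 569 in ERP against MEP, 424 in MKP against MEP and 511 in MKP against ERP. The secondary comparisons gave 35 genes in ERP against CMP and 1005 in MKP against CMP. A fit with the donor as a block called 4536, 3186, 2274, 3534, 251 and 4565 genes. It shared all calls of the fit without it, except 1 in MKP against ERP. Within the 14 libraries the counts were 4041, 2878, 2224, 2967, 64 and 3922, and within the 8 libraries 1035, 507, 731, 742, 192 and 1534. The counts with MKP in the 14 libraries set 1 donor against 3 donors. With libraries summed per donor the counts were 592, 221, 123, 115, 3 and 294. All named genes called in a main comparison had the same sign in both classes and were called with the block. Of these calls 35 were lost with libraries summed per donor and 47 within the 8 libraries. The largest rises and falls were named only where the libraries of the groups did not overlap. Their same sign in both classes follows from that rule and is no separate support. In the 4 main comparisons, 20 of 38, 14 of 31, 15 of 28 and 12 of 31 called named genes had log2 fold changes more than 1 apart between the classes.

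**Figure D3:**
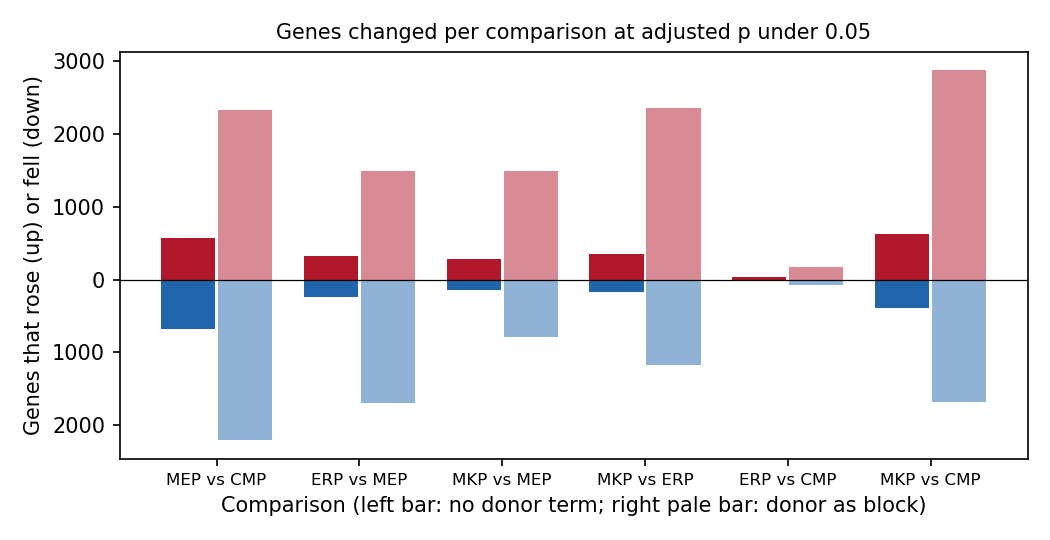
Number of genes that rose and fell at adjusted p under 0.05 in each comparison, with the left bar from the fit without a donor term and the pale right bar from the fit with the donor as a block. The counts of the pale bars are larger in all 6 comparisons, from 251 against 35 in ERP against CMP to 4565 against 1005 in MKP against CMP.

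Against CMP, the libraries labelled MEP held more RNA of erythroid, heme, basophil and mast cell, and ribosome biogenesis genes, and less of stem cell genes. GATA1 (chromosome X, 48786554 to 48794311), the transcription factor shared by the erythroid and megakaryocytic lineages, rose by a log2 fold change of 5.86 (SE 0.63) from 3.98 ± 4.07 CPM to 279 ± 65.3 CPM (SD, n = 4 donors each). KLF1 (chromosome 19, 12884422 to 12887199), the erythroid Krüppel-like factor, rose by 6.59 (SE 0.94). HLF (chromosome 17, 55265012 to 55325065), a transcription factor of blood stem cells, fell by 5.69 (SE 0.45) from 98.3 ± 9.59 CPM to 1.66 ± 0.83 CPM. Within the classes the log2 fold changes were 7.04 and 4.87 for GATA1, 6.62 and 5.86 for KLF1, and −6.14 and −5.13 for HLF. The names of the deposited tables make this a comparison of ERP with CMP.

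Of 22 erythroid genes tested, 17 rose, 0 fell and 5 did not pass, and 19 rose and 1 fell when adjusted over the list alone (camera adjusted p = 5.24e-46). TFRC, the transferrin receptor, rose by 2.55 to 1496 ± 378 CPM, TFR2 by 5.41 and CNRIP1 by 7.63. In heme synthesis and iron import, 8 of 16 genes rose and 0 fell, 12 adjusted over the list alone and 13 with the block (camera adjusted p = 2.14e-14). Among them were ALAD, an enzyme of the heme pathway, at 1.85 and STEAP3, an iron reductase, at 2.48. Basophil, mast cell and eosinophil genes rose in 10 of 17 cases and fell in 0, 14 adjusted over the list alone and 16 with the block (camera adjusted p = 9.72e-29). HDC (chromosome 15, 50241947 to 50266026), which makes histamine, rose by 6.46 (SE 0.67) from 21.4 ± 13.8 CPM to 2068 ± 687 CPM, with 7.38 and 4.90 within the classes. CPA3, a mast cell protease, rose by 2.55, and MS4A2, a chain of the high-affinity IgE receptor, by 9.13.

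Stem and multipotent progenitor genes fell in 15 of 20 cases and rose in 0, 19 adjusted over the list alone (camera adjusted p = 3.27e-26), with NPR3 at −1.64 and MECOM at −1.91. Of 20 granulocyte and monocyte progenitor genes, 2 rose, 2 fell and 16 did not pass, with the same counts adjusted over the list alone and 2 and 4 with the block (camera adjusted p = 0.477). CSF3R, the G-CSF receptor, was at −3.03, FLT3 at −3.65 and MS4A3, which is also expressed by basophils, at 7.54. RNASE2, an eosinophil ribonuclease chosen after its value was seen, was at 3.88. In S phase, 9 of 22 genes rose and 0 fell, 18 both when adjusted over the list alone and with the block. MCM2, MCM5 and MCM7, parts of the replicative helicase, rose by 1.78, 1.35 and 1.08. The camera adjusted p was 1.34e-13, and the adjusted p was 0.0689 with an estimated correlation. Ribosome biogenesis and MYC genes rose in 11 of 23 cases and fell in 0, 14 adjusted over the list alone and 19 with the block (camera adjusted p = 4.2e-11), with MYC at 2.72, WDR12 at 1.35 and NOP58 at 1.04. In G2 and M phase CCNB2, CENPF and TPX2, chosen after their values were seen, rose by 1.88, 1.87 and 1.12 among 23 genes, 7 adjusted over the list alone and 9 with the block, with a camera adjusted p of 9.89e-08, and the adjusted p was 0.272 with an estimated correlation.

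Among the largest rises, HBB and COL6A5 had 0 reads in CMP and were at least 605-fold and at least 426-fold higher in MEP, the latter at least 390-fold by the mean over donors. CLC, the eosinophil and basophil granule protein, had 2 reads in CMP, both in replicate 1, and a ratio of 1760 (95% interval 487 to 14600). APOC1 had 1 read in CMP, in the same library, and a ratio of 1240 (222 to 48900). Without that library both had 0 reads in CMP and were at least 889-fold and at least 312-fold higher in MEP. With all libraries CDH1 rose by 9.24. The largest falls were AVP at −8.31, ACE at −7.31, JAML at −7.21, PREX2 at −6.40, SETBP1 at −6.30 and LAG3 at −6.29. FLI1, a transcription factor of the megakaryocytic lineage, was at −1.13, and the call held with the block. In all, 572 genes rose and 679 fell, and 2330 rose and 2206 fell with the block.

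The comparison of ERP with MEP asks which genes change as the bipotent progenitor commits to red cells. By the labels, erythroid, heme, basophil and S phase genes were lower in ERP and stem cell and some platelet genes higher. By the names of the deposited tables every direction is the reverse. KLF1 fell by 3.31 (SE 0.80) from 332 ± 310 CPM to 32.4 ± 28.3 CPM (SD, n = 4 donors each), and GATA1 fell by 1.94 (SE 0.53). HLF rose by 4.50 (SE 0.42) to 43.3 ± 16.7 CPM. FLI1 (chromosome 11, 128686535 to 128813267) rose by 1.40 (SE 0.21). In the classes KLF1 was at −3.35 and −2.70.

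Erythroid genes fell in 13 of 22 cases and rose in 0, with 18 falls and 1 rise adjusted over the list alone and 19 and 1 with the block (camera adjusted p = 1.3e-34). TFRC was at −1.96, CA1, a carbonic anhydrase of red cells, at −8.32 and TRIB2 at −5.33, and for TRIB2 1 library labelled MEP lay above the others. Of 16 heme genes 7 fell and 0 rose, 9 adjusted over the list alone and 13 with the block (camera adjusted p = 1.68e-16). STEAP3 was at −3.07, ALAD at −1.56 and TMEM14C, a mitochondrial heme synthesis factor for which 1 library labelled MEP lay above the others, at −1.65. Basophil, mast cell and eosinophil genes fell in 6 of 17 cases and rose in 0, 9 adjusted over the list alone and 10 with the block (camera adjusted p = 1.01e-17), with HDC at −4.28, MS4A2 at −4.82 and CLC at −8.42. In S phase 9 of 22 genes fell and 0 rose, 18 adjusted over the list alone and 20 with the block (camera adjusted p = 5.09e-22), and MCM2, MCM5 and MCM7 were at −1.80, −1.35 and −1.06. Of 23 genes of G2 and M phase 4 fell, CCNB2 at −2.12, CENPF at −1.67, MKI67 at −1.43 and TPX2 at −1.41, chosen after their values were seen. Adjusted over the list alone 12 fell, and 13 with the block. Its camera adjusted p was 6.72e-16, and the adjusted p was 0.0538 with an estimated correlation.

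Of 30 megakaryocyte and platelet genes, 7 rose, 1 fell and 22 did not pass, 10 and 5 adjusted over the list alone and 11 and 5 with the block (camera adjusted p = 7.28e-06). SELP, the platelet adhesion protein P-selectin, rose by 6.11, VWF, the von Willebrand factor, by 4.82 and ESAM by 3.43, and the fall was that of ITGA2B at −1.87, chosen after its value was seen. Stem and multipotent progenitor genes rose in 11 of 20 cases and fell in 0, 16 adjusted over the list alone and 17 with the block (camera adjusted p = 2.42e-25), among them NPR3 at 1.48 and CRHBP at 2.86. The largest other rises were PREX2 at 5.62, SLC1A6 at 5.42, SETBP1 at 5.16 and EMCN at 4.71, where SLC1A6 had 1 library labelled ERP and 1 labelled MEP above the others. APOC1 had 0 reads in labelled ERP and was at least 427-fold lower, or at least 367-fold by the mean over donors and at least 277-fold without ERP replicate 4. CDH1 was at −8.27, TGM2 at −7.75 and GRTP1 at −7.40, the last with 1 library of each group above the others. In all, 329 genes rose and 240 fell, against 1496 and 1690 with the block.

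The comparison of MKP with MEP asks which genes change on commitment to the platelet lineage. Platelet, RUNX1 target and cytoskeleton genes were higher in MKP than in the libraries labelled MEP, and erythroid and basophil genes lower. VWF (chromosome 12, 5948874 to 6124770) rose by 8.65 (SE 0.80) from 1.87 ± 1.13 CPM (SD, n = 4 donors) to 643 ± 620 CPM (n = 2 donors). FLI1 rose by 2.48 (SE 0.23) to 411 ± 46.6 CPM. MKP replicate 2 stood apart in genes of monocytes, chosen after their values were seen, with CD14 at 38.01 CPM, LYZ at 318 CPM and S100A8 at 30.7 CPM. The other MKP libraries were at up to 0.805, 25.6 and 0.282 CPM, and without replicate 2 the count of changed genes was 360. Within the classes VWF was at 6.53 and 11.31, and FLI1 at 2.42 and 2.47. The names of the deposited tables make this a comparison of MKP with ERP.

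Megakaryocyte and platelet genes rose in 24 of 30 cases and fell in 0, 27 adjusted over the list alone (camera adjusted p = 3.04e-76), with PDLIM1 at 1.93. Of 24 RUNX1 targets tested, 13 rose and 0 fell, and 15 rose and 1 fell adjusted over the list alone (camera adjusted p = 6.9e-25). SELP rose by 8.60 and PPBP, a platelet chemokine, by 7.90, where 1 library labelled MEP lay above the others for PPBP and the classes gave 10.86 and 5.28. This list shares 15 of its 25 genes with the platelet list, and of the 10 others ALOX12 and MYL9, chosen after their values were seen, rose by 3.88 and 3.98. In the actin, myosin and integrin cytoskeleton 10 of 24 genes rose and 0 fell, 13 rose and 1 fell adjusted over the list alone, and 17 rose and 1 fell with the block (camera adjusted p = 8.78e-18). ACTN1, an actin crosslinker, rose by 2.29, VCL, the adhesion protein vinculin, by 2.25 and ITGA6, an integrin chain, by 2.82. In G2 and M phase 4 of 23 genes rose, 14 adjusted over the list alone and 16 with the block (camera adjusted p = 8.58e-20), with MKI67, the proliferation marker, at 2.68, PLK1 at 3.04 and CDC20 at 2.97. The fourth was TPX2 at 1.17, chosen after its value was seen.

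Erythroid genes fell in 6 of 22 cases and rose in 0, 14 and 3 adjusted over the list alone and 13 and 2 with the block (camera adjusted p = 2.57e-13), with TFRC at −1.90, CA1 at −6.13 and TRIB2 at −6.60. Basophil, mast cell and eosinophil genes fell in 9 of 17 cases and rose in 0, 11 adjusted over the list alone (camera adjusted p = 2.45e-24), with HDC at −5.72, MS4A2 at −5.52 and CLC at −8.95. The largest rises included LRRC32, with 0 reads in labelled MEP and at least 447-fold higher, and KALRN at 9.26 and ITGB3, the platelet integrin beta chain, at 9.01, each with 1 library labelled MEP above the others. XIRP1, with both reads in 1 library, and PKHD1L1 each had 2 reads in labelled MEP and ratios of 938 (95% interval 259 to 7750) and 687 (190 to 5690). Without MEP replicate 2 XIRP1 was at least 458-fold higher, and without MEP replicate 6 the ratio of PKHD1L1 was 1260. CDH6, at 35.7 ± 47.2 CPM in MKP, had 3 reads in labelled MEP and a ratio of 331 (113 to 1610), which was 911 without MEP replicate 6, 649 without MKP replicate 1 and 161 without MKP replicate 4. Among the largest falls ADD2, an erythrocyte membrane skeleton gene, was at −7.45, FAM178B at −7.59 and PDE3B at −7.11. CDH1 had 1 read in MKP and a ratio of 0.000643 (1.63e-05 to 0.00358), which was 0.00151 without MKP replicate 1, and without MKP replicate 3 CDH1 was at least 488-fold lower. For PDE3B and CLC 1 MKP library held every MKP read. In all, 281 genes rose and 143 fell, against 1487 and 787 with the block. KLF1 was at −3.44 with an adjusted p of 0.0673, at −1.77 with 0.0115 with the block, and at −1.72 with 0.0618 with the block and libraries summed per donor. Within the classes KLF1 was at −3.26 (adjusted p = 0.156) and −2.77 (adjusted p = 0.00578). The −3.26 sets MKP of 1 donor against MEP of 3 donors. In that 1 donor KLF1 was at 27.77 and 35.99 CPM in MKP and at 52.03 and 56.15 CPM in MEP. MEP of the other donors of this class was at 519.1 and 671.2 CPM.

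MKP against ERP contrasts the committed progenitors of both lineages. Cell cycle genes, platelet genes and RUNX1 targets were higher in MKP than in the libraries labelled ERP. MKI67 (chromosome 10, 128096659 to 128126385) rose by 4.11 (SE 0.39) from 8.11 ± 3.01 CPM (SD, n = 4 donors) to 142 ± 5.52 CPM (n = 2 donors). ITGA2B (chromosome 17, 44372180 to 44389505), the platelet integrin alpha chain, rose by 4.35 (SE 0.55) from 128 ± 76.9 CPM to 2734 ± 579 CPM. Within the classes MKI67 was at 3.92 and 4.51, and ITGA2B at 4.83 and 3.66. Without MKP replicate 2, which stood apart in the monocyte genes, the count of changed genes was 460. The names of the deposited tables make this a comparison of MKP with MEP.

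In G2 and M phase 18 of 23 genes rose and 0 fell, 23 adjusted over the list alone (camera adjusted p = 3.51e-53), with TPX2, a spindle protein, at 2.58 and CCNB2, a mitotic cyclin, at 3.41. In S phase 12 of 22 genes rose and 0 fell, 20 adjusted over the list alone and 22 with the block (camera adjusted p = 1.8e-30). PCNA, the replication clamp, rose by 2.03, RRM2 by 4.49 and MCM7 by 1.21. Platelet genes rose in 18 of 30 cases and fell in 0, 24 adjusted over the list alone (camera adjusted p = 4.58e-46), with PDLIM1 at 2.35, PLEK, a platelet signalling protein, at 3.23 and LTBP1 at 7.60. RUNX1 targets rose in 10 of 24 cases and fell in 0, with 16 rises and 1 fall adjusted over the list alone and 17 and 1 with the block (camera adjusted p = 4.65e-20). PF4 and PPBP, platelet chemokines, rose by 11.77 and 11.30, and of the 10 targets outside the platelet list ALOX12 and F13A1, chosen after their values were seen, rose by 3.52 and 6.62. The cytoskeleton list had 7 rises and 1 fall among 24 genes, 15 and 1 adjusted over the list alone and 18 and 1 with the block (camera adjusted p = 7.76e-15), with ACTN1 at 3.22, TPM1 at 1.58 and ITGA6 at 1.46. The fall was that of PXN at −1.26, chosen after its value was seen. Among 22 erythroid genes 2 rose and 0 fell, 7 adjusted over the list alone and 9 with the block. Their median log2 fold change was −0.023. As a list they were higher in MKP with a camera adjusted p of 0.000983, and the adjusted p was 0.0962 with an estimated correlation.

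Stem and multipotent progenitor genes fell in 4 of 20 cases and rose in 0, 11 adjusted over the list alone and 16 with the block (camera adjusted p = 1.4e-10), with HLF at −2.02. The others were NPR3, MECOM and MSRB3, the last chosen after its value was seen, at −1.01, −1.24 and −1.27. Without MKP replicate 1 MECOM was not called at −1.30, and without replicate 2, 3 or 4 neither NPR3, at −0.97, −0.88 and −0.87, nor MECOM, at −1.15, −1.29 and −1.21, was called. With the block and libraries summed per donor MECOM was not called either, at −0.91 (adjusted p = 0.0916). LRRC32 and PTGER3 had 0 reads in labelled ERP and were at least 523-fold and at least 674-fold higher in MKP, the latter at least 545-fold by the mean over donors. Without ERP replicate 4 these bounds were 339 and 437, and without MKP replicate 1 that of PTGER3 was 308. CDH6 had 1 read there and a ratio of 1160 (95% interval 208 to 46000). The ratio was 755 without ERP replicate 4, 2280 without MKP replicate 1 and 564 without MKP replicate 4, and without ERP replicate 2 CDH6 was at least 270-fold higher. KALRN rose by 9.92, with 1 library labelled ERP above the others. The largest falls were SDR42E1 at −3.77, for which 1 MKP library lay below the others at 0 reads, and BAIAP3 at −3.25. In all, 345 genes rose and 166 fell, against 2364 and 1170 with the block. Without MKP replicate 3 the count was 320 and without MKP replicate 4 it was 329.

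**Figure D4:**
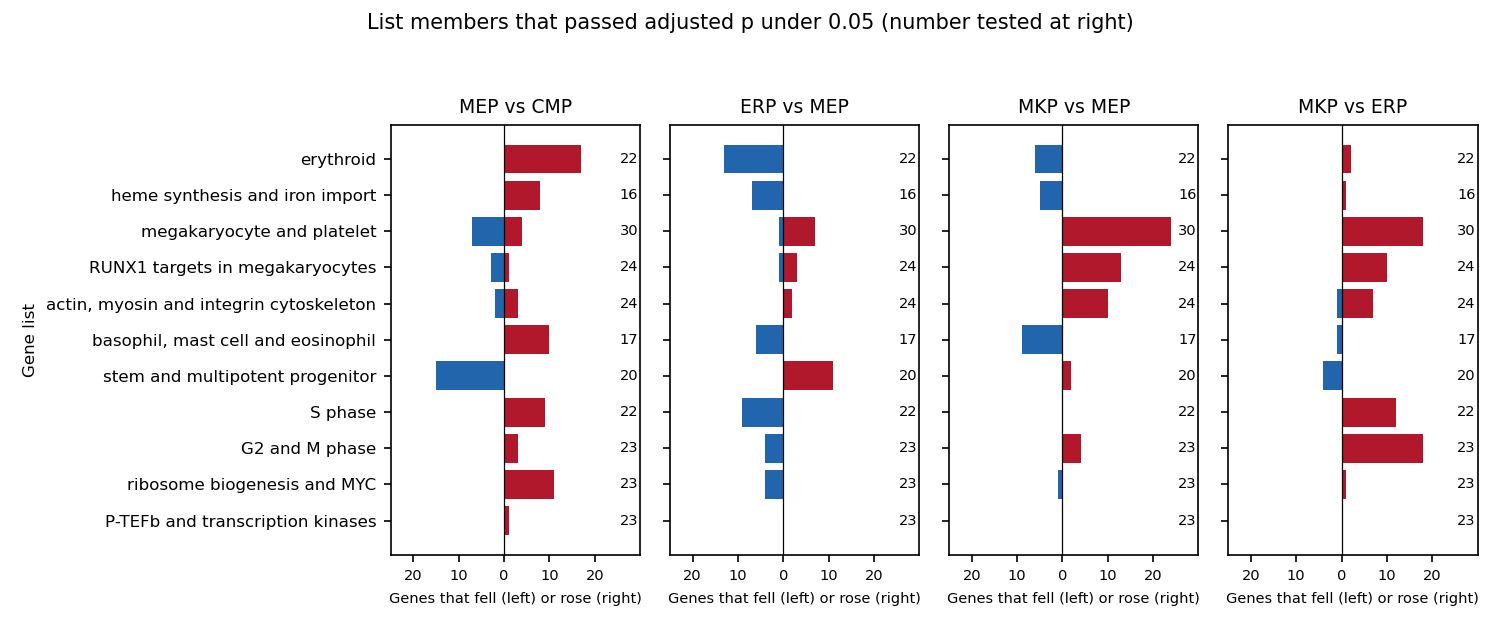
Number of genes that rose (red, right) and fell (blue, left) at adjusted p under 0.05 in 11 gene lists and the 4 main comparisons by labelled population, with the number of genes tested at the right. Megakaryocyte and platelet genes rose in 24 of 30 cases in MKP against MEP, and erythroid genes in 17 of 22 in MEP against CMP.

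RUNX1 (chromosome 21, 34787801 to 36004667), the transcription factor named in the series title, was at 163 ± 111 CPM in CMP, 125 ± 82.6 CPM in MEP, 156 ± 125 CPM in ERP (SD, n = 4 donors each) and 226 ± 197 CPM in MKP (n = 2 donors). Its level did not pass the test in any of the main comparisons. In MKP against MEP its log2 fold change was 0.77 (95% interval −0.54 to 2.08, adjusted p = 0.807), and 0.24 and 0.48 within the classes. The 0.24 sets MKP of 1 donor against MEP of 3 donors. In that 1 donor RUNX1 was at 86.5 and 87.2 CPM in MKP and at 49.85 and 55.0 CPM in MEP. In MEP against CMP its log2 fold change was −0.40 (95% interval −1.59 to 0.79, adjusted p = 0.902), and −0.42 and −0.43 within the classes. With the donor block the log2 fold changes in MKP against MEP and in MEP against CMP were 0.60 (adjusted p = 0.00411) and −0.42 (adjusted p = 0.00974). With the block and libraries summed per donor they were 0.59 (adjusted p = 0.0996) and −0.36 (adjusted p = 0.113). ERP against MEP gave 0.36 (adjusted p = 1) and MKP against ERP 0.40 (adjusted p = 0.92), with 0.29 and 0.31 with the block, which did not pass.

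Genes around RUNX1 were followed with further lists. Among 13 genes of the RUNX and core binding factor family, TLE1, a corepressor, rose in MEP against CMP by 4.88 and was at −5.27 in ERP against MEP. RUNX2 was the called member in MKP against MEP at −2.14 and in MKP against ERP at −2.20, and 1 library labelled MEP lay below the others for RUNX2. CBFB, the partner that binds DNA with RUNX1, passed in none of the main comparisons. In MKP against ERP it was at −0.52 (adjusted p = 0.866) and at 0.49 (adjusted p = 0.0318) with the block. The call was lost with the block and libraries summed per donor, at 0.44 (adjusted p = 0.171), and the classes gave −1.20 and 0.63, which did not pass. The −1.20 sets MKP of 1 donor against ERP of 3 donors. In that 1 donor CBFB was at 38.2 and 40.4 CPM in MKP and at 29.3 and 28.3 CPM in ERP. Of 13 kinases and phosphatases acting on RUNX1, CDK2 rose by 0.83 and DAPK1 fell by 0.80 in MEP against CMP. DAPK1 rose by 0.81 in ERP against MEP, fell by 1.38 in MKP against ERP, and no member was called in MKP against MEP, where 5 rose with the block. Adjusted over the list alone, the core binding factor list had 1, 1, 2 and 1 calls in the 4 main comparisons and the kinase and phosphatase list 2, 2, 3 and 2. With the block, 3 rose and 3 fell, 2 and 3, 2 and 1, and 3 and 3 in the core binding factor list, and 1 and 2, 4 and 1, 5 and 0, and 5 and 1 in the kinase and phosphatase list.

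CDK9, the kinase of the elongation factor P-TEFb, was at 124 ± 77.3 CPM in CMP, 93.0 ± 39 CPM in MEP, 99.4 ± 54.9 CPM in ERP and 89.1 ± 34.7 CPM in MKP and passed in none of the main comparisons or with the block. In MEP against CMP it was at −0.22 in the 14 libraries (adjusted p = 0.783) and passed in the 8 libraries at −0.80 (adjusted p = 0.0358). Of 23 genes of P-TEFb and transcription kinases, CDK7 rose by 0.90 in MEP against CMP, with 0 calls when adjusted over the list alone and 0 by DESeq2, and 1 rise and 2 falls with the block. In ERP against MEP, MKP against MEP and MKP against ERP, 0 of 23 were called by edgeR and 0 by DESeq2, with 2, 2 and 0 at an unadjusted p under 0.05 and 4, 1 and 1 changed with the block. The camera adjusted p of these 3 lists in the 4 main comparisons lay between 0.111 and 0.995. With the block it passed for the kinases and phosphatases acting on RUNX1 in MKP against MEP (adjusted p = 0.00432, and 0.0384 with an estimated correlation). In MKP against ERP, GATA1 was at 1.64 (adjusted p = 0.165) and at 1.94 (adjusted p = 0.0036) with the block, which held at 1.96 (adjusted p = 0.0405) with libraries summed per donor. The classes gave 2.35 (adjusted p = 0.00448) and 0.69 (adjusted p = 0.347), where the 2.35 sets MKP of 1 donor against ERP of 3 donors. KLF1 there was at −0.13 (adjusted p = 0.987) and at 1.34 (adjusted p = 0.035) with the block. That call was lost with summed libraries at 1.52 (adjusted p = 0.0559). The classes gave 0.09 and −0.08, where the 0.09 sets MKP of 1 donor against ERP of 3 donors. In that 1 donor KLF1 was at 27.77 and 35.99 CPM in MKP and at 5.915 and 3.277 CPM in ERP. ERP of the other donors of this class was at 47.66 and 64.4 CPM. FLI1 rose in MKP against ERP by 1.08. In MKP against MEP, GATA1 was at −0.30 (adjusted p = 0.975) and CDK9 at −0.04.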

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

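The tests on the neutrophil, monocyte and basophil genes, and the genes CD14, LYZ and S100A8, were chosen only after the result was seen.

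Erythroid genes were lower in all 6 libraries labelled ERP than in all 6 labelled MEP, by −3.34 in mean log2 CPM (ERP minus MEP). An exchange of the names MEP and ERP in the sample labels predicts this difference, and the names of the deposited tables have that exchange for all 12 samples. An exchange of the labels therefore stays open as a hypothesis, found and tested on the same data. A gate for MEP that took in more erythroid-committed cells, with the labels right, stays open too, as does a biological difference between the sorted populations, which was not tested. Such a gate does not by itself account for CD36 in labelled ERP at 4.06 ± 3.89 CPM, against 5.28 ± 7.52 CPM in CMP, but erythroid genes as a list were higher in labelled ERP than in CMP (camera adjusted p = 1.83e-24), as both would have it.

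A signal in reads no comparison used was that a median of 56.7% of reads lay outside genes in 14 libraries of 3 donors, against 15.6% to 21.2% in 8 libraries of 1 donor. If reads of an unstranded library were counted on 1 strand, genes antisense to an abundant gene should take up its reads in the 14 libraries, and the log2 ratio of antisense to sense CPM was higher there by a median of 4.22 (bootstrap SD 0.16) over 784 pairs. Unspliced RNA may add to it, since sense intronic genes summed to a median of 922 CPM (761 to 1250) in the 14 libraries and to 495 to 724 CPM in the 8. Genomic DNA cannot be told apart, because olfactory receptor genes at a median of 57.3 CPM (30.5 to 71.8) in the 14 libraries overlap the 22.9 to 37.3 CPM of the 8, and unstranded counting raises them too. The labels name a stranded kit for all libraries, the class coincides with 1 donor, and no biological explanation was tested.

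Basophil, mast cell and granule genes were higher in libraries labelled MEP than in those labelled ERP, with HDC at 2068 CPM in labelled MEP. Of 10 basophil, mast cell and eosinophil genes, 6 had a log2 fold change MEP over ERP above 1 in both library classes, between the bounds set for and against such progenitors in the gate. CPA3, PRG2 and SLC45A3 were at −0.33, −1.91 and −0.05 in the 8 libraries and EPX was not tested there. PRG2 lay near the floor in the 8 libraries, at up to 0.478 CPM in labelled MEP and up to 1.26 CPM in labelled ERP. Neutrophil and monocyte progenitors cannot be told apart either, since 7 of their genes had a median of 0.941 (SE of the median 1.21), with ELANE at 4.33, PRTN3 at 4.72 and CSF3R at −2.11. ELANE was not called (adjusted p = 0.18) and lay near the floor, at 1.89 CPM in labelled MEP and 0.087 CPM in labelled ERP. MPO, outside these 7 genes and chosen after its value was seen, was at 97.4 ± 76.3 CPM in labelled MEP. It was at 4.2 ± 6.0 CPM in labelled ERP and at 103 ± 52.9 CPM in CMP. The sort on CD34 is meant to remove mature cells but not their progenitors, which may share a gate. The counts do not measure its purity, and the biological difference between the populations stays untested.

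Among 241 groups of libraries tested, 30 held 1 library far from the others, where chance gives about 12, or 1 in 20, if levels are normally spread. Levels near 0 CPM are not spread in this way. Where all other libraries had 0 reads, any read set 1 library apart, so nothing is concluded from the excess over 12. In CMP the outlying libraries were at 0.0497 CPM for APOC1 and 0.0993 CPM for CLC, with the others at 0, and at 15.1 CPM for CD14. In labelled MEP they lay above the others for CD14 at 12.5 CPM, CDH6 at 0.327 CPM, GRTP1 at 30.6 CPM, ITGB3 at 0.868 CPM, KALRN at 0.816 CPM, PKHD1L1 at 0.163 CPM, PPBP at 4.21 CPM, S100A8 at 4.01 CPM, SLC1A6 at 1.93 CPM, TMEM14C at 272 CPM, TRIB2 at 402 CPM and XIRP1 at 0.102 CPM. RUNX2 lay below the others there, at 25.8 CPM. In labelled ERP they were at 16.4 CPM for CD14, 8.36 CPM for S100A8, 0.0386 CPM for CDH6, 0.193 CPM for GRTP1, 0.655 CPM for KALRN, 49.2 CPM for SLC1A6 and 23.4 CPM for ZNF608. In MKP they were at 0.402 CPM for CDH1, 0.161 CPM for CLC and 0.202 CPM for PDE3B, with the others at 0, and at 0 CPM for SDR42E1, with the others from 1.21 to 1.40 CPM. There 1 library lay above the others for CD14 at 38.01 CPM, LYZ at 318 CPM and S100A8 at 30.7 CPM.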

How the results depend on the processing

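Fits within library classes and the fit of summed libraries with a donor block were chosen after the data were examined. DESeq2 size factors, at least 1 CPM in 4 libraries and the fold threshold left all 6 counts of changed genes within 1.5 times of those reported, and leaving out MKP replicate 1 or 2 did so for the 3 counts with MKP. The other settings moved some or all of them. Several of these settings had fewer libraries or tested more genes, and the cause was not tested. In the order MEP against CMP, ERP against MEP, MKP against MEP, MKP against ERP, ERP against CMP and MKP against CMP, the counts without an alternative were 1251, 569, 424, 511, 35 and 1005. They were 4536, 3186, 2274, 3534, 251 and 4565 with the donor block, 1936, 1122, 933, 994, 93 and 1812 with the DESeq2 Wald test, and 592, 221, 123, 115, 3 and 294 with libraries summed per donor. The block in the 2 donors with all populations gave 2647, 1573, 1401, 2557, 182 and 3152, and the donor block with summed libraries 4496, 2932, 1206, 2163, 62 and 3269. In the 14 libraries the counts were 4041, 2878, 2224, 2967, 64 and 3922, and in the 8 libraries 1035, 507, 731, 742, 192 and 1534. Those with MKP in the 14 libraries set 1 donor against 3 donors. A block by replicate number, which sets libraries of 1 donor apart where a donor gave more than 1 per population and could be fitted for CMP, MEP and ERP alone, gave 5139 in MEP against CMP, 3766 in ERP against MEP and 273 in ERP against CMP. Without a filter, where 36113 genes were tested, the counts that moved were 830 in MEP against CMP, 329 in ERP against MEP, 323 in MKP against ERP and 638 in MKP against CMP. Fits of the compared groups alone gave 368 in ERP against MEP, 269 in MKP against MEP, 282 in MKP against ERP and 17 in ERP against CMP.

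Leaving out each donor in turn gave 524 to 4041 in MEP against CMP, 174 to 2878 in ERP against MEP, 140 to 2224 in MKP against MEP, 88 to 2967 in MKP against ERP, 14 to 64 in ERP against CMP and 315 to 3922 in MKP against CMP. The highest count came each time without the donor of the 8 libraries. Leaving out each MKP library in turn gave 305 to 360 in MKP against MEP, 320 to 460 in MKP against ERP and 635 to 961 in MKP against CMP, and in MKP against ERP the counts were 320 without replicate 3 and 329 without replicate 4, and 635 and 659 in MKP against CMP. In MKP against ERP the falls of BTBD11, CRYBG1, GIMAP1, MECOM, NPR3 and ZNF608 passed with all libraries at −2.59, −2.82, −2.58, −1.24, −1.01 and −2.79, and some of these calls were lost in each such fit. The log2 fold changes of the lost calls were CRYBG1 −3.14, GIMAP1 −2.90 and MECOM −1.30 without MKP replicate 1. Others were BTBD11 −2.30, MECOM −1.15, NPR3 −0.97 and ZNF608 −2.39 without MKP replicate 2. Others were BTBD11 −2.46, CRYBG1 −2.89, MECOM −1.29, NPR3 −0.88 and ZNF608 −2.59 without MKP replicate 3. Others were BTBD11 −2.50, CRYBG1 −2.99, GIMAP1 −2.36, MECOM −1.21, NPR3 −0.87 and ZNF608 −2.90 without MKP replicate 4. With exchanged MEP and ERP names 35 genes changed in MEP against CMP and 1251 in ERP against CMP, by construction.

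The same exchange turned the sign of 44 named values that passed without or with it, and of others that passed in neither, and it ended 45 further calls. In ERP against MEP the log2 fold changes became ALAD 1.56, APOC1 10.25, CA1 8.32, CDH1 8.27, CLC 8.42, CRHBP −2.86, DAPK1 −0.81, EMCN −4.71, ESAM −3.43, FLI1 −1.40, GATA1 1.94, GRTP1 7.40, HDC 4.28, HLF −4.50, KLF1 3.31, MCM2 1.80, MCM5 1.35, MCM7 1.06, MS4A2 4.82, NPR3 −1.48, PREX2 −5.62, SELP −6.11, SETBP1 −5.16, SLC1A6 −5.42, STEAP3 3.07, TFRC 1.96, TGM2 7.75, TLE1 5.27, TMEM14C 1.65, TRIB2 5.33 and VWF −4.82. In MEP against CMP they became APOC1 −1.11, DAPK1 0.011, FLI1 0.27, MCM2 −0.017, MCM5 −0.0021, STEAP3 −0.59 and TLE1 −0.39, none of which passed. In MKP against MEP they became CA1 2.20 and TFRC 0.055, and in MKP against ERP GIMAP1 0.21, HLF 2.47, MECOM 0.42 and NPR3 0.46, of which HLF passed.

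With the donor block 2 named values of MKP against ERP turned and passed, CBFB at 0.49 and KLF1 at 1.34. With the block and libraries summed per donor they kept this sign at 0.44 and 1.52 and did not pass (adjusted p = 0.171 and 0.0559). RUNX1 passed with a block, at −0.42 (donor), −0.43 (replicate number) and −0.55 (2 donors) in MEP against CMP, and at 0.60 (donor) and 0.58 (2 donors) in MKP against MEP. Its adjusted p over the alternatives ranged from 0.00562 to 1 in the first and from 0.00411 to 1 in the second, and it did not pass with the block when libraries were summed per donor. DESeq2 size factors kept the direction of the named values that passed and ended 3 calls. More calls of named values were lost elsewhere, 35 with libraries summed per donor, 47 in the 8 libraries, 16 in fits of the compared groups alone, 12 without a filter, and 15, 15, 2 and 49 with each donor left out in turn. The share of rises among called genes was 52.4% with the DESeq2 Wald test against 67.5% in MKP against ERP, 45.6% against 61.7% in MKP against CMP and 74.2% against 91.4% in ERP against CMP. With an estimated correlation, the lists that changed numbered 7 in MEP against CMP (12 with the preset), 7 in MKP against MEP (13), 7 in MKP against ERP (16), 5 in ERP against CMP (13) and 10 in MKP against CMP (17), and in the 8 libraries 10 lists changed in MKP against ERP. The difference between libraries labelled ERP and MEP in the erythroid list was −3.43 per donor (exact permutation p = 0.125, the smallest that 4 pairs allow) and −2.86 in the 8 libraries (exact permutation p = 0.333, the smallest 6 regroupings allow).

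Other splits of the libraries of 2 compared groups were fitted, 60 per comparison, a draw that was not uniform. It held the real split, at least 1 split that follows the library class, and every split that exchanges libraries of the same replicate number (32, where both groups had 6 libraries) or keeps the donors of the MKP libraries (36). As many genes changed in 1 of the 60, the real one, for 3 comparisons. These were MEP against CMP (1251, highest other 130), ERP against MEP (569, highest other 0) and ERP against CMP (35, highest other 0). No other fitted split of single libraries reached the real count there. This cannot exclude chance, because these splits take libraries of 1 donor as separate. The other splits also mix the populations in both groups, which can add to the spread. Exchanges of whole donors are too few for a share under 0.05. In the comparisons with MKP as many genes changed in 2 of 60, the real split and that of the library class. The latter gave 6621 genes for MKP against MEP, 6251 for MKP against ERP and 5535 for MKP against CMP. These many calls point to the library class as a structure of the samples. Among the 36 splits with matched donors, the highest other counts were 3, 1 and 31. The counts with the block and within classes are given above. The 36 splits with matched donors also take libraries of 1 donor as separate and cannot exclude chance. Exchanges of whole donors, 2 with MKP, are too few for a share under 0.05. What limited the calls was not settled, since the spread between donors holds that of the library class, which coincides with 1 donor. Depth was not varied. Simulated 2-fold changes were recovered in 4.48% of cases for MEP against CMP and 0% for MKP against ERP without a donor term, and in 35.8% and 41.8% at the spread of the fit with one. The simulated libraries were independent, with no donor or class effect.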

Other observations

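All genes named in this part were chosen after their values were seen. Few genes separated the libraries labelled ERP from CMP, 32 that rose and 3 that fell. With the block 178 rose and 73 fell. GATA1 rose by 3.93, TFR2 by 3.19, CNRIP1 by 4.71 and the delta-globin gene HBD by 4.31, and 4 of 22 erythroid genes rose, 8 with the block and 11 adjusted over the list alone (camera adjusted p = 1.83e-24). Of 17 basophil, mast cell and eosinophil genes 3 rose, 9 with the block and 6 adjusted over the list alone (camera adjusted p = 2.18e-21), with MS4A2 at 4.31, CPA3 at 1.89 and FCER1A at 3.63. MPO, the neutrophil granule enzyme, fell by 4.86. By the names of the deposited tables this is a comparison of MEP with CMP.

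MKP differed from CMP by 620 rises and 385 falls, and by 2881 and 1684 with the block. Platelet genes rose in 20 of 30 cases, 25 adjusted over the list alone (camera adjusted p = 4.68e-45), G2 and M phase genes in 17 of 23, 23 adjusted over the list alone (camera adjusted p = 5.1e-34), and erythroid genes in 12 of 22, 14 adjusted over the list alone (camera adjusted p = 4.85e-15). Of 20 genes of the interferon response 4 fell, 10 adjusted over the list alone and 9 with the block, with BST2 at −2.31, XAF1 at −1.65, IRF7 at −1.24 and IFI44L at −2.58. Its camera adjusted p was 7.37e-07, and the adjusted p was 0.0591 with an estimated correlation. In cholesterol synthesis FDPS, INSIG1 and EBP rose by 1.09, 1.03 and 0.93 among 20 genes, 4 adjusted over the list alone and 12 with the block (camera adjusted p = 0.000211). RUNX2 fell by 2.53 and KIT, the stem cell factor receptor, by 1.98.

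Further lists were tested in MEP against CMP. Of 30 megakaryocyte and platelet genes 4 rose and 7 fell, 4 and 8 adjusted over the list alone and 5 and 10 with the block (camera adjusted p = 0.167). The rises were ITGA2B at 3.73, LTBP1 at 2.29, P2RY1 at 1.55 and PDLIM1 at 1.39, and the falls included SELP at −4.46, ESAM at −3.67 and VWF at −3.48. Of 24 cytoskeleton genes MYH10, FLNA and TPM1 rose by 1.16, 1.05 and 0.87, and ITGA6 and PXN fell by 2.36 and 1.60, with 6 and 5 adjusted over the list alone and 9 and 5 with the block (camera adjusted p = 0.645). Of 24 RUNX1 targets ITGA2B rose and 3 fell, among them SELP and MEIS1, with 3 and 4 adjusted over the list alone and 6 and 5 with the block (camera adjusted p = 0.775). Of 22 megakaryocytic-erythroid transcription factors GATA1 and KLF1 rose and FLI1, ERG and MEIS1 fell, the last 2 by 0.98 and 1.51, with 8 rises and 7 falls with the block (camera adjusted p = 0.486). Of 16 surface proteins used in sorting 4 rose and 4 fell (camera adjusted p = 0.236), with CD36 at 4.68, CD38 at 1.84, ITGA2B at 3.73 and TFRC at 2.55, and among the falls CD34 at −0.70, FLT3 at −3.65 and PTPRC at −1.52. Of 21 cytokine receptor and signalling genes CSF2RB, EPOR and STAT5A rose by 5.15, 3.99 and 0.61, and 7 fell, among them IL6R at −3.14 and SOCS3 at −2.81. Their camera adjusted p was 0.0304, and the adjusted p was 0.122 with an estimated correlation. Of 10 endothelial genes ROBO4, PECAM1, EGFL7 and ERG fell by 4.71, 1.49, 1.10 and 0.98 (camera adjusted p = 0.000108), 6 with the block. CLEC9A and TCF4 of 6 dendritic genes fell by 4.21 and 1.19 (camera adjusted p = 0.000372), 3 with the block, and LTB of 12 lymphoid genes was at −3.82 (camera adjusted p = 0.316), 2 with the block.

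In the same comparison BST2 fell by 1.16 among 20 interferon genes, 8 with the block, with a camera adjusted p of 0.00115, and the adjusted p was 0.268 with an estimated correlation. HSPA8 of 20 immediate early and heat shock genes rose by 0.80 (camera adjusted p = 0.126), while 1 rose and 13 fell with the block (camera adjusted p = 6.38e-07). UQCRC2 of 20 genes of oxidative phosphorylation rose by 0.67, 8 with the block, with a camera adjusted p of 0.0105, and the adjusted p was 0.272 with an estimated correlation. Of 8 mature monocyte, 6 T and NK, and 20 cholesterol genes, 0 were called by edgeR without the block and 0 by DESeq2, while with the block 4 cholesterol genes rose and 1 fell, with 1, 0 and 3 at an unadjusted p under 0.05. Their camera adjusted p was 0.775, 0.57 and 0.125. Adjusted over the list alone, the calls, rises then falls, were 3 and 5 for the transcription factors, 5 and 4 for surface proteins, 4 and 8 for cytokine genes, 1 and 6 for endothelial, 0 and 3 for dendritic, 0 and 2 for lymphoid and 0 and 5 for interferon genes, and 1 and 0 for both the heat shock and the oxidative phosphorylation list.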
